A study of Homo sapiens with 9 samples.

How the data were processed

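Total RNA of Panc1 cells, an established human pancreatic cancer line, was labelled with biotin and hybridised to Affymetrix whole-transcript gene arrays, 1 array per sample. RNA was extracted with the mirVana kit, per the labels' protocols. The 9 arrays fall into 3 groups of 3, which the labels give as unstimulated controls, controls given TRAIL for 5 h, and cells given TRAIL for 5 h with an siRNA against RelA. Whether the controls received a non-targeting siRNA is not given in the labels used here. A description field of the labels speaks of primary tissue, while the title, source and treatment fields give cell culture; the samples were treated as cell culture.

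The deposited values are log2 expression values per probe set, made by the authors with RMA, per the submitters' processing notes; RMA corrects background, quantile normalizes between arrays and summarizes the probes of a probe set. The RMA software version, the summary level and the annotation used are not given in the sources used here. The median log2 value per array lay between 5.43 and 5.49 over all 33297 probe sets, so the arrays had been brought to a common scale before deposit. Such scaling removes any difference in total RNA per cell, and the compression of RMA values at low signal makes fold changes of weakly expressed genes too small. Scanner intensities were not used here, so signal over local background was not assessed; the number of arrays limits the precision.

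Probe sets were named through the platform's probe table. That table lists 21214 of the probe sets, 19460 with 1 gene symbol and 1754 with several, and the other 12083 are unnamed here. Of the probe sets with 1 symbol, 19429 were matched by gene number to the RefSeq gene table of assembly GRCh38.p14, which was used for current symbols only; no coordinates are given. A gene was represented by its probe set with the highest mean over all arrays, which left 18417 genes, 769 of them with more than 1 probe set. Probe sets with no symbol or several symbols were tested apart and are not named.

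Differences were tested with limma (lmFit and eBayes without trend, two-sided) on the log2 values of all 9 arrays, which share 1 estimate of the spread, with 6 residual and 4.81 prior degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all 18417 genes. The 3 comparisons were TRAIL against unstimulated, RelA siRNA with TRAIL against TRAIL, and RelA siRNA with TRAIL against unstimulated. For RELA itself an exact permutation test was added, whose smallest two-sided p for 3 against 3 arrays is 0.1. The 21 gene lists covered NF-kB family subunits, NF-kB inhibitors and feedback regulators, chemokines, cytokines and colony-stimulating factors, anti-apoptotic genes, TRAIL receptors and death signalling, interferon-stimulated genes, immediate early and AP-1 genes, adhesion and protease genes, epithelial and mesenchymal genes, ER stress, p53 targets, cell cycle, cholesterol biosynthesis, hypoxia and glycolysis, oxidative stress, MHC class I and antigen presentation, ribosomal proteins, and markers of leukocytes, of fibroblasts and endothelium, and of pancreatic acinar and islet cells. The interferon and MHC class I lists share 3 members. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry.

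The comparisons, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the NF-kB subunits, the 10 genes raised and the 10 lowered with the largest change among those that passed and moved the same way in all 3 replicate numbers, up to 4 members of each list with the smallest p, and the 10 genes with the largest TRAIL change in each overlap of the comparisons. Genes outside it are said to be chosen after their values were seen.

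The replicate number was taken from a title suffix shared across the groups; the labels do not say what it stands for, nor that replicates came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. Deviations from the group means correlated between arrays of the same number in all 9 pairs (0.216 to 0.382) and not between other arrays (-0.253 to -0.0475), so the numbers pair the arrays. The fit with the replicate number as a block was an alternative fixed beforehand, and its value stands beside named genes, list counts and total counts where it ends or adds a call or moves the count by over 1.5 times. No arrays were duplicates: the smallest SD of the difference between 2 arrays of a group was 0.254 on the log2 scale, and correlations over all probe sets were 0.993 to 0.996. All sample columns of the table were used.

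The test was checked on simulated data built from the spread of these arrays, over 18417 genes per comparison. For TRAIL against unstimulated, without the block, it recovered 70.15% of genes changed by 0.5 on the log2 scale and 98.5% of those changed by 1. For RelA siRNA with TRAIL against unstimulated it recovered 59.7% of those changed by 0.5. The changed genes were drawn at random and no simulated array stood apart. These shares therefore do not describe genes in which 1 real array stood apart. False calls were 1.105%, 1.105% and 1.149% of calls in the 3 comparisons without the block, and 4.975%, 6.796% and 6% with it. The comparisons that share the TRAIL control arrays were set against 100 simulated draws without effects. Alternatives were the replicate block, leaving out genes below the median level of 6.33 (log2), a prior with trend and robust estimation, array weights, a renewed quantile normalization, centring each array on its median, the mean of a gene's probe sets, all probe sets, only the 2 groups compared, other thresholds, and leaving out each array. Leaving out a replicate number in all groups together, the subunit list without RELA, draws for comparisons that share other arrays and assignments of the arrays within replicate numbers were added after seeing the data. Computations used R 4.3.3 with limma 3.58.1 and version 1.17.8 of the package data.table, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.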

Results

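Gene expression was measured in 9 samples of Panc1 cells, 3 unstimulated, 3 given TRAIL for 5 h, and 3 given TRAIL for 5 h together with an siRNA against RelA. TRAIL is a death ligand of the tumour necrosis factor family whose receptors can start apoptosis and can also activate the transcription factor NF-kB. RelA is an NF-kB subunit, encoded by RELA. The design asks which genes respond to TRAIL and how the TRAIL-treated profile differs when RelA is depleted. It holds no unstimulated RelA siRNA group, so effects of the siRNA that do not need TRAIL cannot be separated here from effects on the TRAIL response. All values below are log2 expression values or log2 differences with the standard error of the limma fit, n = 3 arrays per group.

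RELA mRNA was lower on each of the 3 RelA siRNA arrays than on any other array. Its log2 values were 10.41, 10.25 and 10.17 on the unstimulated arrays, 10.46, 10.52 and 10.54 on the TRAIL arrays, and 9.29, 8.90 and 8.82 on the RelA siRNA arrays. Against TRAIL alone, RELA was 2.83-fold lower (SE 0.116 on the log2 scale, adjusted p = 9.8e-05), at 35.3% of the control level. Against unstimulated cells it fell by 1.27 (SE 0.116, adjusted p = 0.000266). A two-sided exact permutation test of RELA gave p = 0.1 in both comparisons, the smallest value that 3 against 3 arrays allow. The TRAIL arrays differed from the unstimulated arrays in RELA by 0.23 (SE 0.116, adjusted p = 0.446), which did not pass.

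**Figure D1:**
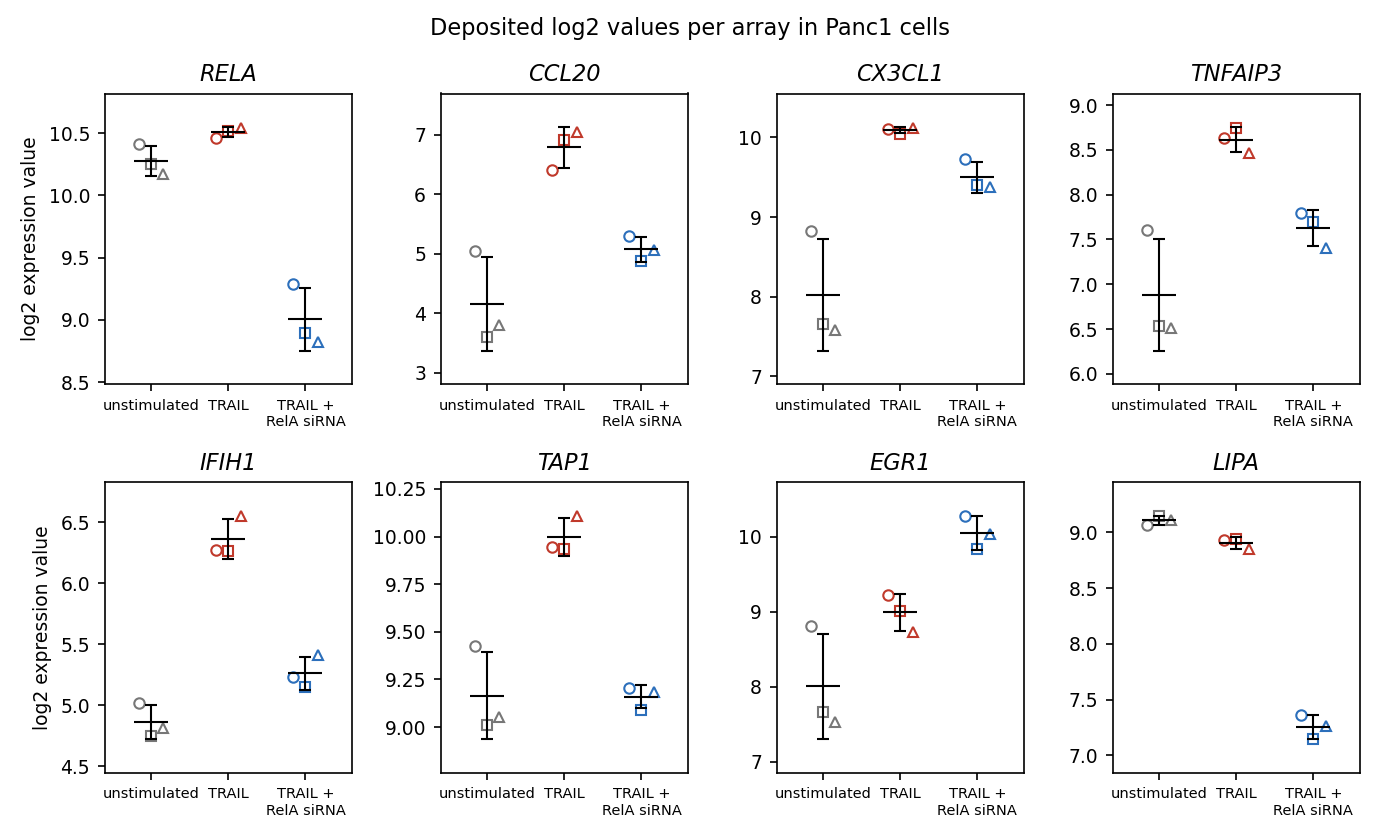
Deposited log2 values (vertical axes) of 8 genes on each of the 9 arrays, in the 3 groups named on the horizontal axes; circle, square and triangle are replicates 1, 2 and 3, and black lines are the mean and SD of the 3 arrays. RELA lies at 8.82 to 9.29 on the RelA siRNA arrays, IFIH1 and TAP1 rise with TRAIL and lie lower with the siRNA, and EGR1 is highest with the siRNA.

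TRAIL raised 165 genes, among them 9 of 17 NF-kB feedback regulators, 6 of 15 chemokines and 2 of 27 adhesion and protease genes. CCL20, a chemokine that attracts lymphocytes and dendritic cells, rose 6.21-fold (log2 2.63, SE 0.315, adjusted p = 0.0061, limma with Benjamini-Hochberg adjustment), and CX3CL1, the membrane-bound chemokine fractalkine, rose 4.20-fold (SE 0.263 on the log2 scale). TRAF1, an adaptor of tumour necrosis factor receptors, rose 3.83-fold (SE 0.339), CXCL8, encoding interleukin-8, 3.71-fold (SE 0.267), and the transcription factor IRF1 3.66-fold (SE 0.236). ICAM1, a leukocyte adhesion molecule, rose 3.48-fold (SE 0.336), and CD83, a surface protein of activated antigen-presenting cells, 3.43-fold (SE 0.195). TNFAIP3, encoding the NF-kB inhibitor A20, rose 3.32-fold, TNFAIP2 3.15-fold and the guanylate-binding protein gene GBP4 3.10-fold. The genes lowered by TRAIL changed less. TET1, a DNA demethylase gene, fell by 0.82 (SE 0.108, adjusted p = 0.00681), the R-spondin receptor gene LGR4 fell by 0.74 (SE 0.123), the hyaluronan synthase gene HAS2 fell by 0.70 (SE 0.107), and TXNIP, an inhibitor of thioredoxin, fell by 0.63 (SE 0.115). CCL20, GBP4 and TET1 have mean levels below the median gene.

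Of the 5 NF-kB subunit genes, RELB, REL and NFKB1 rose with TRAIL. RELB changed by 1.00 (SE 0.202) and REL by 0.67 (SE 0.13), while NFKB2, at 1.10, missed the threshold (adjusted p = 0.0541; 0.034 with the replicate block), so that 4 rose adjusted over the list alone. Among 17 inhibitors and feedback regulators of NF-kB, 9 rose, including NFKBIA, which encodes the inhibitor IkB-alpha, by 1.58 (SE 0.255), TNIP1 by 0.80 and BCL3 by 0.60. Here 13 rose with the block, 13 rose adjusted over the list alone, and TNIP3 fell by 0.28, a member chosen after its value was seen. Of 15 chemokine genes 6 rose, among them CXCL1 by 1.45 (SE 0.209), with 9 raised and CCL28 (-0.18, chosen after its value was seen) lowered adjusted over the list alone. TNF at 1.22 (SE 0.101), the interleukin subunit gene EBI3 at 1.45 (SE 0.161) and CSF1 at 0.90 were the 3 of 20 cytokine genes that rose, against 7 adjusted over the list alone. The mean log2 shift over all members was 0.81 for the subunits, 0.60 for the feedback regulators, 0.84 for the chemokines and 0.32 for the cytokines, with camera adjusted p = 7.16e-08, 2.54e-18, 2.11e-13 and 1.11e-06. The feedback and chemokine lists also passed at adjusted p = 0.0289 and 0.0449 with an estimated correlation, and both calls were lost when the replicate block was added to it (adjusted p = 0.121 each). The subunits had adjusted p = 0.0674 and the cytokines adjusted p = 0.0516 with an estimated correlation.

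Genes that restrain apoptosis and genes that promote it both included raised members. Of 14 anti-apoptotic genes, 4 rose with TRAIL, or 9 adjusted over the list alone; besides TRAF1 these were BCL2A1 at 0.90 (SE 0.184), a BCL2 relative, TNFAIP8 at 0.58 and the mitochondrial superoxide dismutase gene SOD2 at 0.49. Their mean shift was 0.45, with camera adjusted p = 1.07e-09 and adjusted p = 0.0449 with an estimated correlation, which rose to adjusted p = 0.121 with the block as well. Of 26 genes of TRAIL receptors and death signalling, FAS, encoding another death receptor, rose by 1.10 (SE 0.2) and PMAIP1, encoding the BH3-only protein NOXA, rose by 0.57 (SE 0.0886). The TRAIL receptor gene TNFRSF10B changed by 0.69 and did not pass over all genes (adjusted p = 0.0586; 0.0137 with the replicate block). With the block 7 anti-apoptotic and 4 death signalling genes rose over all genes. In the latter list 7 rose adjusted over the list alone, and the mean shift was 0.12, with camera adjusted p = 0.0197 and adjusted p = 0.0924 with an estimated correlation.

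Of 29 interferon-stimulated genes 6 rose with TRAIL, and of 9 measured MHC class I genes 3, or 7 and 4 with the replicate block. IFIH1, encoding the RNA sensor MDA5, rose 2.83-fold (SE 0.108 on the log2 scale, adjusted p = 0.000566) and was among the raised interferon-stimulated genes, with IRF1, TAP1 at 0.83 (SE 0.107) and IFIT3 at 0.67. Adjusted over the list alone 8 rose and IFIT1 fell by 0.48 (adjusted p = 0.0152 over all genes with the block), a member chosen after its value was seen. The mean shift was 0.28, with camera adjusted p = 3.45e-06 and adjusted p = 0.0516 with an estimated correlation. In the MHC class I list 7 rose adjusted over the list alone. The 3 raised over all genes were the peptide transporter gene TAP1, the immunoproteasome gene PSMB9 at 0.64 and the peptidase gene ERAP1 at 0.37; TAP1 and PSMB9 stand in both lists. The mean shift was 0.38, with camera adjusted p = 9e-10 and adjusted p = 0.0468 with an estimated correlation, a call lost with the block as well (adjusted p = 0.121).

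Of 25 immediate early and AP-1 genes, 5 rose with TRAIL, or 9 with the replicate block and 15 adjusted over the list alone, and all 25 had a positive difference. JUNB rose by 0.89 (SE 0.116) and JUND by 0.47 (SE 0.0781), both AP-1 subunits, while the MAP kinase phosphatase gene DUSP5 rose by 0.99 (SE 0.195) and the mRNA decay factor gene ZFP36 by 0.53. The mean shift was 0.45, with camera adjusted p = 2.13e-17 and adjusted p = 0.0651 with an estimated correlation. Of 27 adhesion and protease genes, ICAM1 and PLAU, encoding the protease urokinase, rose, the latter by 0.72 (SE 0.131), and 5 rose with the block and 7 adjusted over the list alone; the mean shift was 0.24, with camera adjusted p = 1.82e-05 and adjusted p = 0.0651 with an estimated correlation. The cell cycle list had a negative mean. No member of that list passed in limma, over all genes or adjusted over the list alone, and the mean shift over 29 genes was -0.10, with camera adjusted p = 0.0012, adjusted p = 0.275 with an estimated correlation and a fry adjusted p = 0.0561.

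The other 10 lists did not shift with TRAIL. Camera gave adjusted p = 0.68 for epithelial and mesenchymal genes, 0.991 for ER stress genes, 0.299 for p53 targets, 0.107 for hypoxia genes, 0.54 for oxidative stress genes and 0.0927 for ribosomal proteins, whose fry adjusted p was 0.0158 at a mean shift of 0.04. Cholesterol biosynthesis genes had adjusted p = 0.0952, and 0.0378 with the replicate block, with a mean of -0.14. The p53 targets held CDKN1A, a cyclin-dependent kinase inhibitor gene raised by 0.83 (SE 0.162), and the stress cytokine gene GDF15, which fell by 0.64 (SE 0.129). PLK3 (0.66) among the p53 targets and PPP1R15A (0.74) among the ER stress genes passed adjusted over the list alone, and over all genes with the replicate block (adjusted p = 0.0406 and 0.0325), where 2 p53 targets rose and 1 fell, and 1 ER stress gene rose and 1 fell. Markers of leukocytes, of fibroblasts and endothelium and of pancreatic acinar and islet cells had adjusted p = 0.864, 0.834 and 0.834. No marker passed over all genes; adjusted over the list alone the leukocyte marker CD14 changed by -0.30. The leukocyte list's mean was -0.01 although its median was 0.02 and its test pointed up.

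In total 202 of 18417 genes passed with TRAIL, 165 raised and 37 lowered, and 42 of the raised genes changed at least 2-fold against 0 of the lowered. With the replicate block 457 passed, 291 raised and 166 lowered. The unstimulated array of replicate 1 stood apart: over the 165 raised genes it lay above the mean of the other 2 unstimulated arrays by a median of 0.314, and the TRAIL shift of each of the 10 raised lists was smallest for replicate 1. Without that array 867 genes passed, among them all 202. Without unstimulated replicate 2 or 3 the count was 34 or 33, and without TRAIL replicate 1, 2 or 3 it was 107, 47 or 39. The calls of RELB, BCL2A1 and GDF15 were lost with a renewed quantile normalization, and those of RELB, ICAM1 and DUSP5 with a prior with trend and robust estimation.

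Of 1095 genes that differed between RelA siRNA with TRAIL and TRAIL alone, 102 had also passed with TRAIL and 993 had not. Against TRAIL alone, CCL20 was 3.27-fold lower with RelA siRNA (log2 -1.71, SE 0.315, adjusted p = 0.0105, limma with Benjamini-Hochberg adjustment), GBP4 2.63-fold (SE 0.239), EBI3 2.45-fold (SE 0.161) and CD83 2.28-fold (SE 0.195). LIPA, encoding lysosomal acid lipase, was 3.14-fold lower (log2 -1.65, SE 0.0744, adjusted p = 4.32e-06), PEX19, needed for peroxisome assembly, 2.42-fold (SE 0.0841) and CLNS1A, encoding a chloride channel regulator and spliceosome assembly factor, 2.23-fold (SE 0.1). The genes with the largest rise were MXRA5, a matrix remodelling gene, at 2.70-fold (log2 1.43, SE 0.137, adjusted p = 0.000367), ZC3HAV1L at 2.68-fold (SE 0.104) and TMEM65 at 2.64-fold (SE 0.129). ACLY, encoding the citrate lyase that supplies acetyl-CoA for lipid synthesis, rose 2.55-fold (SE 0.0961), the pseudokinase gene TRIB2 2.51-fold (SE 0.15), the transcription factor gene ETV1 2.37-fold (SE 0.137) and the drug transporter gene ABCC3 2.35-fold (SE 0.117).

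With RelA siRNA 6 of 17 feedback regulators, 3 of 15 chemokines and 3 of 20 cytokines fell. Besides RELA, no subunit gene passed: REL changed by -0.46 (adjusted p = 0.0637; 0.0204 with the replicate block), NFKB1 by -0.56 (adjusted p = 0.136; 0.0275 with the block), RELB by -0.39 and NFKB2 by -0.40. In this list 3 were lower with the block, RELA among them, and 3 adjusted over the list alone. Of 17 feedback regulators 6 fell, including TNFAIP3 by 0.99 (SE 0.243), TNIP1 by 0.71, OPTN by 0.68 and BCL3 by 0.43; with the block 11 fell and 1 rose, and adjusted over the list alone 12 fell and N4BP1 rose by 0.36 (adjusted p = 0.0145 over all genes with the block), a member chosen after its value was seen. NFKBIA changed by -0.44 (adjusted p = 0.354). Of 15 chemokine genes CCL20, CCL5 (-1.06, SE 0.167) and CXCL1 (-0.88, SE 0.209) fell, or 4 with the block and 6 adjusted over the list alone, while CXCL8 changed by -0.82 (adjusted p = 0.102; 0.029 with the block) and CX3CL1 by -0.59 (adjusted p = 0.226). EBI3, TNF (-0.85, SE 0.101) and IL32 (-0.62) were the 3 of 20 cytokine genes that fell, against 4 with the block and 4 adjusted over the list alone. Mean shifts were -0.66 for the subunits, -0.36 for the feedback regulators, -0.45 for the chemokines and -0.18 for the cytokines, with camera adjusted p = 0.000178, 7.57e-08, 0.000137 and 0.0401. The subunit list holds RELA, the target of the siRNA; without it, a setting added after seeing the data, the other 4 had a mean of -0.45, with 2 lower adjusted over the list alone, camera adjusted p = 0.0167 and adjusted p = 0.474 with an estimated correlation. None of the 4 calls with RELA included held at adjusted p = 0.254, 0.146, 0.183 and 0.413 with an estimated correlation, and the cytokine call was also lost with the block (adjusted p = 0.0623).

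Of 29 interferon-stimulated genes 9 fell with RelA siRNA, over all genes and adjusted over the list alone, including IFIH1 by 1.10 (SE 0.108), RIGI, another RNA sensor gene, by 1.03 (SE 0.161), TAP1 by 0.84 (SE 0.107) and IFIT3 by 0.74. The mean shift was -0.29, with camera adjusted p = 1.11e-05 and adjusted p = 0.146 with an estimated correlation. Of 9 MHC class I genes TAP1, PSMB9 (-0.76, SE 0.133), TAP2 (-0.68, SE 0.0922) and ERAP1 (-0.33) fell, 4 over all genes and 4 adjusted over the list alone, at a mean shift of -0.39 with camera adjusted p = 6.47e-06 and adjusted p = 0.162 with an estimated correlation.

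Of 14 anti-apoptotic genes 4 fell with RelA siRNA, or 6 with the block and 6 adjusted over the list alone: BCL2L1, encoding BCL-xL, by 0.67 (SE 0.0883), BIRC5, encoding survivin, which also acts in mitosis, by 0.55 (SE 0.0846), TNFAIP8 by 0.36 and SOD2 by 0.34. The mean was -0.29, with camera adjusted p = 0.000178 and adjusted p = 0.162 with an estimated correlation. Members of the death signalling list fell too. FAS fell by 0.98 (SE 0.2), BCL2L11, encoding the BH3-only protein BIM, by 0.68 (SE 0.0886), the apoptosome gene APAF1 by 0.60 (SE 0.0807) and BAK1 by 0.42, which are 4 of 26 over all genes and 4 adjusted over the list alone, while 1 rose with the block, at a mean of -0.11 with camera adjusted p = 0.0225 and adjusted p = 0.162 with an estimated correlation.

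Immediate early and AP-1 genes did not shift with RelA siRNA (mean 0.05, camera adjusted p = 0.754). JUND rose by 0.31 (SE 0.0781, adjusted p = 0.044) and was the only gene raised in both comparisons; the RelA siRNA call was lost with each array centred on its median or with only the 2 groups fitted. EGR1 changed by 1.06 without passing (SE 0.279, adjusted p = 0.0509; 0.0115 with the block). With the block 4 of 25 rose and 3 fell, and adjusted over the list alone 2 rose and 3 fell. Adhesion genes did not shift either (adjusted p = 0.218), with the matrix protease gene MMP2 raised by 0.59 (SE 0.0839), TIMP2 raised by 0.49 and the integrin gene ITGB3 lowered by 0.33. Camera gave adjusted p = 0.447 for epithelial and mesenchymal genes, where COL1A1 rose by 0.57, and 0.127 for hypoxia genes, where the angiogenic factor gene VEGFA rose by 0.74 (SE 0.0905) and ALDOC by 0.77. Cholesterol genes had adjusted p = 0.0759, and 0.0201 with the block, with DHCR7 raised by 0.53. ER stress, p53 target, cell cycle, oxidative stress and ribosomal lists had adjusted p = 0.666, 0.66, 0.119, 0.0796 and 0.888, with ZMAT3 lowered by 0.61 among the p53 targets and CCNE2 raised by 0.61 among the cell cycle genes. The ribosomal list had a mean of 0.003 and a test that pointed down. Leukocyte, fibroblast and endothelial, and pancreatic markers had adjusted p = 0.66, 0.66 and 0.754, with CD14 raised by 0.42 and THY1 by 0.56. Adjusted over the list alone, 3 p53 targets rose and 2 fell, and the leukocyte markers FCER1G (-0.37) and ITGAM (-0.33) passed; in the other lists of this paragraph besides the immediate early genes those counts equalled the counts over all genes. With the replicate block more members passed: 5 epithelial and mesenchymal genes rose, 3 ER stress genes rose and 1 fell, 2 p53 targets rose and 2 fell, 2 cell cycle genes rose and 2 fell, 3 cholesterol genes rose, 1 oxidative stress gene rose and 3 fell, 3 adhesion genes fell, and 2 leukocyte markers fell, FCER1G and ITGAM (adjusted p = 0.0318 and 0.016).

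**Figure D2:**
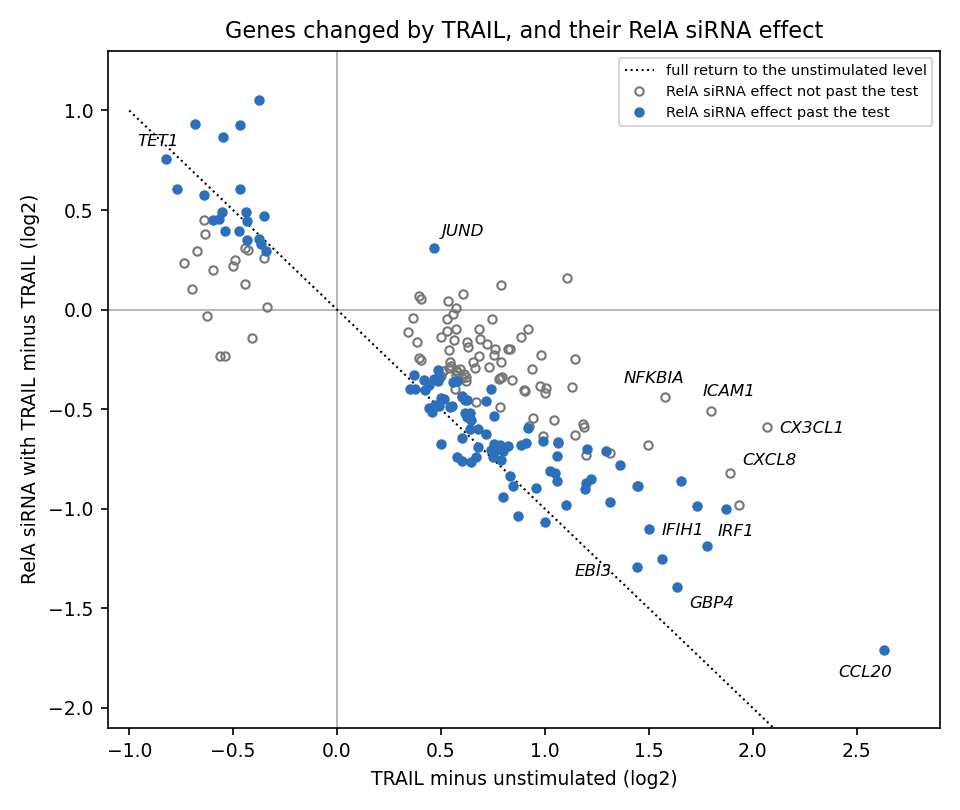
Each of the 202 genes that passed with TRAIL, with its TRAIL effect in log2 units on the horizontal axis and its RelA siRNA effect in log2 units on the vertical axis; filled points passed in both, and the dotted line marks a full return to the unstimulated level. Of the 165 raised genes 157 lie below 0 on the vertical axis, and JUND is the filled point above it.

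Of the 165 genes raised by TRAIL, 81 (49.1%) were lower with RelA siRNA, led by CCL20, IRF1, CD83, TNFAIP3, TNFAIP2 and GBP4. Of the 37 lowered by TRAIL, 20 were higher with the siRNA, led by TET1, IRAK1BP1, CNNM1 and HOXB3. TET1 rose by 0.76 (SE 0.108) and the magnesium transporter family gene CNNM1 by 0.93 (SE 0.0765) with the siRNA. Independent lists would overlap by 4.58 and 1.17 genes, and the one-sided Fisher p was 4.56e-82 and 7.38e-21. Fisher's test takes the genes and the 2 comparisons as independent, which they are not, so these p-values do not measure the spread between samples. Both comparisons share the TRAIL arrays, which cannot be split into 2 parts of at least 2 arrays, so part of the excess may come from them. In 100 simulated draws without effects the overlap was 0 in either direction, which does not measure that part, since calls are rare where no gene has an effect. Across all genes the correlation of the 2 effects was -0.490 against -0.500 in the draws. Groups of equal size that share arrays give about -0.500 without effects, so the correlation does not tell effects from shared arrays. The covariance was -0.0176 against -0.00548 in the draws, whose lowest was -0.00579. In size it was thus larger than the shared arrays gave there. With the replicate block the overlaps were 152 and 80. Assignments of the arrays that kept the replicate numbers were added after seeing the data. The 3 others with the TRAIL arrays as the shared group gave at most 6 and 1. The 4 with all RelA siRNA arrays as the shared group gave 163 to 273 and 129 to 234. The highest of these, 273 and 234, was the 3 real groups with their roles exchanged, and the next was 203 and 172. Without unstimulated replicate 1, 2 or 3 the overlaps were 184, 23 or 22 and 100, 3 or 3. Without TRAIL replicate 1, 2 or 3 the overlaps were 55, 30 or 20 and 9, 3 or 5, and without RelA siRNA replicate 1, 2 or 3 they were 69, 40 or 40 and 12, 8 or 10.

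On the mean over the 165 raised genes, 40.3% ± 3.95 (SD, n = 3 replicate numbers) of the TRAIL rise was left with RelA siRNA. For 100 genes chosen on 2 replicate numbers and measured on the remaining number, a check added after seeing the data, it was 41.3% ± 6.46 (SD, n = 3). Of the mean shift of each list with TRAIL, 38.1% ± 6.65 was left for NF-kB feedback regulators, 40.3% ± 25.3 for chemokines, 40.5% ± 12.4 for cytokines, 31.1% ± 18.3 for anti-apoptotic genes and 8.07% ± 33.9 for the subunits, RELA included, or 47.4% ± 17.8 for the 4 without RELA, added after seeing the data (SD, n = 3 each). It was 72.6% ± 3.49 for adhesion genes, 119% ± 30.6 for immediate early and AP-1 genes, -9.08% ± 13.4 for interferon-stimulated genes, -4.94% ± 11.3 for MHC class I genes, -0.267% ± 40.3 for death signalling and 143% ± 24.5 of the decrease for cell cycle genes. Differences between these shares were not tested. Each share is a ratio of list means, in which members that moved in opposite directions cancel. With RelA siRNA and TRAIL against unstimulated cells, 2 death signalling genes were raised and 2 lowered over all genes. In the anti-apoptotic list 1 was raised and 2 were lowered. A share near 0 therefore does not show that each member returned to the unstimulated level.

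In all, 1095 genes passed between RelA siRNA with TRAIL and TRAIL alone, 584 higher and 511 lower, with 25 and 16 at least 2-fold, and 2246 (1182 higher and 1064 lower) passed with the replicate block. With each array centred on its median, 486 were higher and 646 lower, and without genes below the median level 708 and 778, so which direction holds more genes depends on the processing. Without TRAIL replicate 2 or 3 the count was 534 or 630, and without RelA siRNA replicate 1, 2 or 3 it was 724, 459 or 548.

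Cells with RelA siRNA and TRAIL differed from unstimulated cells in 928 genes, of which 507 had changed in the same direction with the siRNA against TRAIL alone (1031 with the replicate block). Both comparisons share the RelA siRNA arrays, so this count is no separate evidence. The correlation of their effects was 0.601, against 0.501 in simulated draws without effects, and the covariance was 0.0236, against 0.0055. In the draws at most 0 genes were higher and 1 lower in both, against 273 and 234 here. Calls are rare where no gene has an effect, so the draws do not measure the part that comes from the shared arrays. EGR1, an immediate early transcription factor gene, was 4.13-fold higher (log2 2.04, SE 0.279, adjusted p = 0.00283, limma with Benjamini-Hochberg adjustment), CX3CL1 2.79-fold (SE 0.263), the growth factor gene HBEGF 2.64-fold (SE 0.325) and the transcription factor gene NFATC2 2.64-fold (SE 0.315). CREB5 was 2.49-fold higher (SE 0.217), the differentiation inhibitor gene ID3 2.47-fold (SE 0.246) and SERPINB9, encoding a granzyme B inhibitor, 2.41-fold (SE 0.133). LIPA was 3.61-fold lower (log2 -1.85, SE 0.0744, adjusted p = 1.26e-06), TENT5C 3.07-fold (SE 0.271), PEX19 2.67-fold (SE 0.0841), GCA 2.52-fold (SE 0.209) and the DNA damage checkpoint gene RAD17 2.12-fold (SE 0.154). HBEGF and NFATC2 lay at similar levels with TRAIL alone. HBEGF was at 10.14, 10.3 and 10.13 there and at 10.27, 10.28 and 10.17 with the siRNA. NFATC2 was at 8.975, 8.951 and 9.012 there and at 9.169, 9.033 and 8.877 with the siRNA. On the unstimulated arrays HBEGF was at 9.863, 8.16 and 8.505 and NFATC2 at 8.628, 7.146 and 7.102, both highest in replicate 1.

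Of 25 immediate early and AP-1 genes 12 were raised, 13 with the block and 14 adjusted over the list alone, including JUN by 0.87 (SE 0.153), JUND by 0.77 (SE 0.0781) and JUNB by 0.75 (SE 0.116). The mean was 0.50, with camera adjusted p = 6.28e-12, fry adjusted p = 0.0462 and adjusted p = 0.479 with an estimated correlation. The other lists that shifted here did not pass in fry. Its adjusted p was 0.0988 for chemokines, 0.106 for feedback, 0.0919 for hypoxia, 0.0988 for adhesion and 0.066 for cell cycle genes. Chemokines had a mean shift of 0.38, with CX3CL1 and CXCL8 (1.07, SE 0.267) raised and 3 adjusted over the list alone, and the feedback list a shift of 0.23, with NFKBIA raised by 1.14 (SE 0.255) over all genes and adjusted over the list alone; camera gave adjusted p = 0.00537 and 0.0227, and both had adjusted p = 0.479 with an estimated correlation. Hypoxia genes shifted by 0.21, with ANGPTL4 raised by 1.06 (SE 0.237), ALDOC by 0.67 and VEGFA by 0.56, or 5 members adjusted over the list alone. Adhesion genes shifted by 0.17, with PLAU raised by 0.55, TIMP2 by 0.49 and MMP2 by 0.45 and ITGB3 lowered by 0.35, or 5 raised and 1 lowered adjusted over the list alone. Camera gave adjusted p = 0.00352 for the hypoxia and 0.023 for the adhesion list, and adjusted p = 0.479 with an estimated correlation for both. With the block 2 feedback, 5 hypoxia and 6 adhesion genes were raised. Of 29 cell cycle genes 4 fell, among them the mitotic kinase genes BUB1 by 0.41, AURKA by 0.40 and AURKB by 0.33, while CCNE2 rose by 0.65 (SE 0.0862); 10 fell with the block, adjusted over the list alone 9 fell and 1 rose, and the mean was -0.14 with camera adjusted p = 6.13e-05 and adjusted p = 0.479 with an estimated correlation.

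The interferon-stimulated and MHC class I lists did not differ from unstimulated cells past the test (camera adjusted p = 0.541 and 0.988), and no member of either passed over all genes; with the replicate block 2 interferon-stimulated genes were raised and 1 lowered, and 1 MHC class I gene was lowered. IFIH1 lay 0.40 above the unstimulated level (SE 0.108, adjusted p = 0.0596; 0.0298 with the block). Lists of NF-kB subunits, cytokines, anti-apoptotic genes and death signalling had adjusted p = 0.541, 0.0842, 0.197 and 0.668; the last had a mean of 0.003 while its test pointed down. Without RELA the other 4 subunits had a mean of 0.50, camera adjusted p = 0.019 and adjusted p = 0.452 with an estimated correlation. Passing members were RELA, the cytokine gene LIF (0.99, SE 0.237), GADD45B (0.32), BIRC5 (-0.59), BCL2L1 (-0.50), BCL2L11 (-0.53), APAF1 (-0.52), PMAIP1 (0.48) and TNFRSF10D, encoding a TRAIL decoy receptor (0.78, SE 0.159). Adjusted over the list alone 3 subunits, 4 cytokines, 5 anti-apoptotic and 3 death signalling genes were raised, and 1, 0, 2 and 3 lowered; of the interferon-stimulated genes IFIH1 and IRF1 (0.87) were raised and IFIT1 (-0.43) was lowered, the latter 2 with adjusted p = 0.0362 and 0.00867 over all genes with the block. The zinc finger factor gene SNAI1 (0.41) and COL1A1 (0.49) among epithelial and mesenchymal genes, CDKN1A (0.63) and MDM2 (-0.35) among p53 targets and THY1 (0.58) also passed, against 3 raised in the first of these lists and 3 raised and 2 lowered p53 targets adjusted over the list alone. With the block 2 subunits, 2 cytokines, 2 anti-apoptotic and 3 death signalling genes were raised, 3 of the last list lowered, 3 p53 targets raised and 2 lowered, 1 ER stress and 1 cholesterol gene raised and 2 oxidative stress genes lowered. The remaining lists had adjusted p between 0.197 and 0.988; the pancreatic marker list had a mean of -0.01 while its median was 0.04 and its test pointed up.

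**Figure D3:**
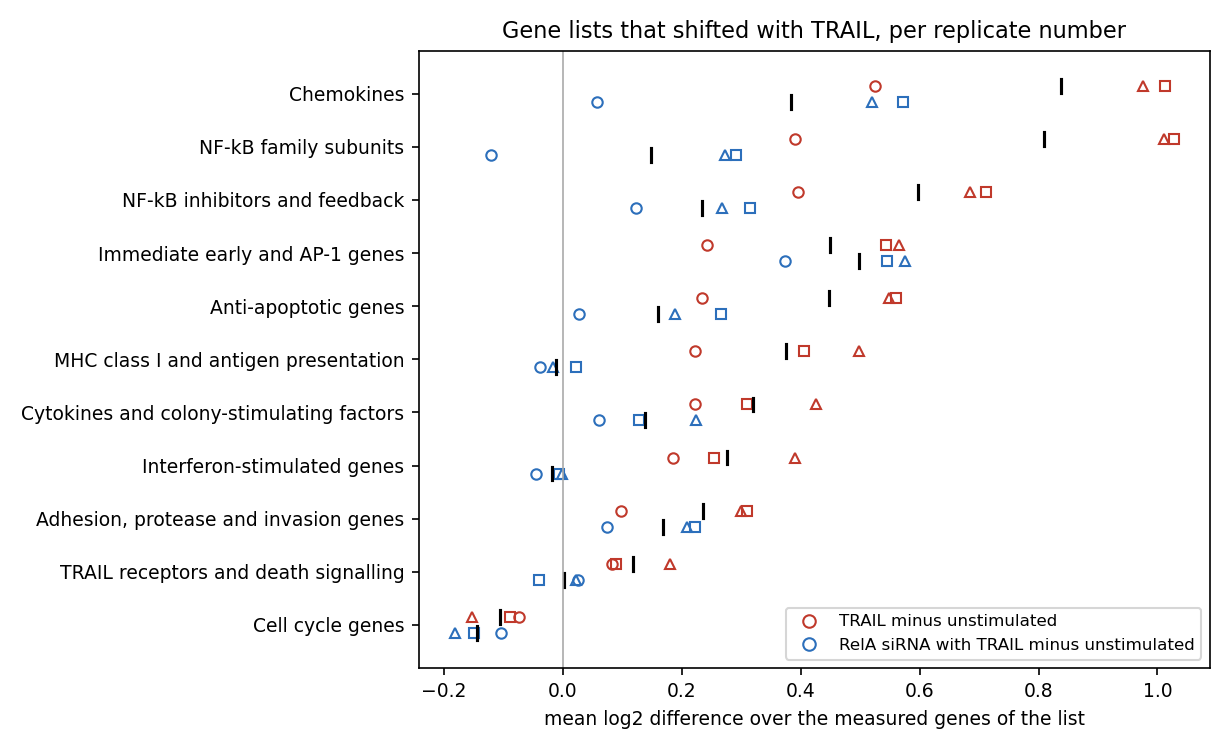
Mean log2 difference over the measured genes of each of the 11 lists that shifted with TRAIL (horizontal axis, log2 units), for TRAIL minus unstimulated in red and RelA siRNA with TRAIL minus unstimulated in blue; circle, square and triangle are replicate numbers 1, 2 and 3, and the black bar is their mean. For interferon-stimulated and MHC class I genes the blue means lie at -0.02 and -0.01, for immediate early and AP-1 genes at 0.50.

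In this comparison 928 genes passed, 495 higher and 433 lower, with 39 and 9 at least 2-fold, and 1842 passed with the replicate block, 911 higher and 931 lower. The direction with more genes turned here too: 441 were higher and 510 lower with each array centred on its median, and 631 and 673 without genes below the median level. Without unstimulated replicate 1, 1310 genes passed, 791 of the 928 among them; without unstimulated replicate 2 or 3 the count was 330 or 399, and without RelA siRNA replicate 1, 2 or 3 it was 451, 354 or 413. Of the other 9 splits of these 6 arrays, 3 put unstimulated replicate 1 with 2 RelA siRNA arrays and gave 10 or 11 shifted lists, against 6 for the real groups. The CXCL8, SNAI1 and CDKN1A calls were lost with each array centred on its median, and the HBEGF call with a prior with trend and robust estimation.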

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

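The tests of a reversal and of a scaling difference behind the RelA siRNA count, both tests of the unstimulated array, the counts without a replicate number in all groups, and the assignments that keep the replicate numbers, were chosen only after the result was seen.

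Probe sets that carry no gene symbol or several symbols entered no comparison of named genes, and some of them passed the limma test there. Of 12083 unnamed probe sets, 5 passed with TRAIL (4 raised, 1 lowered), 76 with RelA siRNA against TRAIL alone (18 raised, 58 lowered) and 73 with RelA siRNA and TRAIL against unstimulated cells (18 raised, 55 lowered). Of 1754 probe sets with several symbols, 16 (4 raised, 12 lowered) and 15 (1 raised, 14 lowered) passed in the last 2 comparisons and 0 with TRAIL, where 161 had an unadjusted p under 0.05.

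RelA siRNA changed 1095 genes against TRAIL alone and TRAIL changed 202. Without the unstimulated array of replicate 1 TRAIL changed 867, and the RelA siRNA count of that fit is not given here. The counts were 896 and 640 without every group's replicate 1, and 41 and 42 genes changed at least 2-fold. A gap stayed with array weights (1769 and 465), with the replicate block (2246 and 457) and with a minimum of 1.5-fold (288 and 129). The size of the gap thus depends on the arrays and the setting. Of the 1095 genes 31.5% had moved the other way with TRAIL at an unadjusted p under 0.05 in limma. That share depends on the power of the TRAIL comparison and on the shared TRAIL arrays. The genes higher with the siRNA had a median TRAIL difference of -0.123 and those lower 0.109. The siRNA differences of the 1095 had a median size of 0.442, which argues against a reversal of the TRAIL response as the whole cause. The 1095 were chosen on their siRNA differences in the same data, which enlarges that size. Part of the gap to the TRAIL medians is therefore built in. Release of transcripts from endogenous microRNAs by competition of the siRNA for the silencing complex would raise microRNA targets. The 40 measured targets, a list outside the 21, did not lie higher. Their median shift was -0.000403 (quartiles -0.151 and 0.0765), with 1 raised and 4 lowered. Camera gave an unadjusted p = 0.193 across genes (n = 40 targets, which are not independent replicates). Whether the microRNAs that repress them are active in these cells was not measured, so this does not decide the question. Medians over the tested genes differed by at most 0.0466 between arrays. A shift of whole arrays left in the deposited values was thus small beside the median siRNA difference of 0.442. With each array centred on its median 1132 genes passed, 486 higher and 646 lower, against 584 and 511 in the main fit. Centring moved the arrays so little that a count near 1095 was likely beforehand, so this count does not test a scaling difference. Scaling that varies with the signal level was not tested. RMA had already brought the arrays to a common scale, so these values cannot show a difference removed before deposit. Open and untested are off-target silencing by the siRNA sequence and effects of RelA that do not need TRAIL. The design has no second siRNA and no unstimulated RelA siRNA group. Whether the controls received a non-targeting siRNA is not given either, so effects of siRNA delivery as such also stay open. Any of these may hold for LIPA and ACLY, for which TRAIL itself did not pass.

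The unstimulated array of replicate 1 lay above the other 2 unstimulated arrays in 146 of the 165 genes raised by TRAIL, by a median of 0.314. ICAM1 was at 11.12 there against 9.58 and 9.50 and NFKBIA at 10.29 against 9.12 and 9.22, while IFIH1 was at 5.02 against 4.75 and 4.81. RNA of TRAIL-treated cells mixed into the sample would carry every raised gene the same part of the way to the TRAIL level. Over the 42 genes raised at least 2-fold that part had an SD of 14 percentage points, against 6.69 between the other 2 unstimulated arrays. It was 8.83% for IFIH1, 12.1% for EBI3, 49.7% for ICAM1 and 57.8% for RELB. This spread argues against mixing as the only source. A difference of replicate 1 would widen the spread too, so mixing together with such a difference is not excluded. Open is a difference shared by the arrays of replicate 1. Its TRAIL array, with a median of -0.0672 relative to the other 2, goes against such a difference. Its RelA siRNA array, at 0.156 and above both others in 116 genes, goes with it. Other sources within the unstimulated sample of replicate 1, a mild activation of NF-kB among them, were not tested.

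Splits of the 6 arrays of a comparison number 10, too few for a share under 0.05. TRAIL changed 202 genes and 11 lists, against at most 0 genes and 10 lists in other splits, and 1 of 10 splits reached each. RelA siRNA against TRAIL alone changed 1095 genes and 8 lists, against at most 0 and 6, and 1 of 10 splits reached each. RelA siRNA with TRAIL against unstimulated changed 928 genes, reached by 1 of 10 splits (highest other 0), and 6 lists, reached by 4 of 10 (highest other 11). The splits with 9 to 11 lists, 3 in each comparison with unstimulated cells, all put unstimulated replicate 1 with 2 treated arrays, so the list counts follow a structure of the samples that includes that array; among splits that part all pairs, the highest other list count was 9, 3 and 11 in the 3 comparisons. For the overlaps, 1 of 100 assignments of the 9 arrays, the real one, gave 81 genes (highest other 2), and 1 of 100 gave 20 (highest other 1), but only 1 of the others called any gene in both comparisons, so these counts decide little. Among 100 assignments that kept the replicate numbers, 5 gave as many genes in each overlap, the real one included. The highest other, 273 and 234, kept the 3 real groups whole and only exchanged their roles, so it is no regrouping. The share counts that real contrast and so does not decide on chance, which is not excluded. The 4 others all had the 3 RelA siRNA arrays as the group shared by both comparisons, so a shared group that stands apart from both other groups gives such an overlap.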

How the results depend on the processing

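The tests that leave out a replicate number in all groups, or RELA from the subunit list, were chosen only after the result was seen; the others were planned. With the replicate block, the counts of changed genes rose to 457 (TRAIL), 2246 (RelA siRNA against TRAIL) and 1842 (RelA siRNA with TRAIL against unstimulated), and the overlaps to 152 and 80; besides calls given with the results it ended none of the 194 named gene calls. Array weights gave 465, 1769 and 1415 genes and overlaps of 144 and 56. A minimum of 1.5-fold left 129, 288 and 225 genes, an adjusted p under 0.1 gave 313, 1934 and 1529, and testing all probe sets gave 46, 616 and 470 probe sets. With only the 2 groups compared, 85 genes passed with TRAIL and 567 in the last comparison. With an estimated correlation in camera 4, 0 and 0 lists shifted, against 11, 8 and 6 (10, 5 and 1 at an unadjusted p under 0.05); with the block as well, none did, at adjusted p of 0.121 or more. For RelA siRNA against TRAIL, 5 lists shifted without weakly expressed genes, and fry gave 2 lists in the last comparison. The other thresholds change their counts by construction; for the rest the cause was not tested.

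Leaving out arrays moved the counts between 0 and 867 with TRAIL, 58 and 896 for RelA siRNA against TRAIL, and 50 and 1310 against unstimulated; the overlaps between 0 and 184 and between 0 and 100; and the shifted lists between 10 and 12, 6 and 10, and 3 and 9. The counts of 0 in limma came without every group's replicate 2 or 3, where 1120 and 1199 genes had an unadjusted p under 0.05 with TRAIL. The highest counts of genes and overlaps, save 896, came without unstimulated replicate 1. RELA stayed lower by log2 -1.669 to -1.395. Of 194 named calls 174 were lost in at least 1 such setting, and none changed sign. A renewed quantile normalization ended 9 named calls (BCL2A1, GDF15, RELB and IRAK1BP1 with TRAIL among them), centring 7, a prior with trend and robust estimation 7 (ICAM1, RELB and DUSP5 with TRAIL among them), only 2 groups 53, and array weights or the mean of probe sets 0. Signal over background was not analysed here.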

Other observations

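The tests of which genes changed by TRAIL still differed from unstimulated cells with RelA siRNA, and most genes named with them, were chosen only after the result was seen.

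Of the 165 genes raised by TRAIL, 33 were still raised against unstimulated cells when RelA siRNA was present, against 4.43 for independent lists. Both comparisons share the unstimulated arrays, so the count is no separate evidence. The correlation of the effects was 0.402, against 0.499 in simulated draws without effects, while the covariance was 0.0138, against 0.00547. At most 1 gene was raised in both in the draws, where calls are rare. SERPINB9, a granzyme B inhibitor gene, rose by 1.11 with TRAIL (SE 0.133) and lay 1.27 above unstimulated with the siRNA (SE 0.133). SOCS1, a feedback inhibitor of cytokine receptors, had 1.13 and 0.74 (SE 0.142 each), the kinase gene IRAK2 1.15 and 0.90 (SE 0.176 each), and the dual-specificity phosphatase gene DUSP8 0.92 and 0.82 (SE 0.146 each). EFNA1, encoding an ephrin ligand, rose by 1.29 with TRAIL, fell by 0.71 between TRAIL and the siRNA with TRAIL (SE 0.108), and still lay 0.58 above unstimulated (adjusted p = 0.0137, limma with Benjamini-Hochberg adjustment). The siRNA effect itself did not pass for SERPINB9, SOCS1, IRAK2 and DUSP8 (adjusted p = 0.531, 0.138, 0.455 and 0.748); SOCS1 had 0.0465 with the replicate block. The count of 33 depends on the arrays: it was 97 with the replicate block, 131 with array weights, 56 without genes below the median level and 276 without unstimulated replicate 1, but 4 without unstimulated replicate 2 or 3, 19, 11 or 11 without TRAIL replicate 1, 2 or 3, and 11, 12 or 15 without RelA siRNA replicate 1, 2 or 3.

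Of the 37 genes lowered by TRAIL, 8 were still lower than in unstimulated cells, against 0.87 for independent lists, in comparisons that share the unstimulated arrays. TXNIP lay at -0.66 (SE 0.115), HAS2 at -0.59 (SE 0.107), LGR4 at -0.50 (SE 0.123), FAM221A at -0.80 and FAM174B at -0.77 against unstimulated, and the siRNA effect on them did not pass. The FAM221A call with TRAIL was lost with a renewed quantile normalization. The count of 8 was 50 with the replicate block, 39 with array weights and 116 without unstimulated replicate 1, and 4 or fewer without any other single array. Among all 37, the share of the TRAIL decrease left with RelA siRNA was 28.1% ± 11.2 (SD, n = 3 replicate numbers), and 9.39% ± 19.9 for 100 genes chosen on 2 replicate numbers and measured on the remaining number. HMOX1, encoding heme oxygenase, differed by -0.95 between RelA siRNA with TRAIL and TRAIL alone without passing (adjusted p = 0.0707; 0.00881 with the replicate block).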
